A study of Bos taurus with 23 samples.

How the data were processed

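RNA from 23 samples of bovine umbilical cord mesenchymal cells was profiled by bulk MARS-Seq, a 3′ tag method for poly(A) RNA, with single reads on an Illumina NovaSeq, per the labels' protocols. Cells grew in low-glucose DMEM with fetal bovine serum, per the labels' protocols. Per the submitters' processing notes, cutadapt, STAR, HTSeq and DESeq were used with the genome build ARS-UCD1.2. Their versions and settings, the annotation release, the use of strand and of molecular identifiers, and any filter on genes are not given in the sources used here. The deposited table held raw counts per gene as whole numbers, not normalized, for 16094 Ensembl gene IDs in 23 columns, and each column was matched to a sample by its name. In the deposited counts 97 genes were at 0 in every library, and no row lacked a gene ID. If identifiers were not collapsed, counts are not independent molecules, so intervals and floors cover counting error only. Because strand use is not given, overlapping and antisense genes may share counts, as may near-identical copies of a gene.

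Groups were taken from the sample titles and treatment labels. Tags in the library names (WJ or BUC, AM or FBS, 2D, and a P number) were used as named, and what they stand for was not assumed. No Ensembl ID could be matched to a symbol in the reference table used, 0 of 16094. The gene lists planned before the data were examined therefore could not be run, nor could the part of the rule for named genes that needs a symbol. The rule took, among genes with an edgeR adjusted p under 0.05 and a mean of at least 10 CPM on the higher side, those with the largest absolute log2 fold change. It was applied to the line against primary cells without the symbol condition, and 2 higher and 2 lower IDs are given. No genome coordinates were used.

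Every comparison was tested with edgeR 4.0.16 in R 4.3.3 on the counts (estimateDisp, glmQLFit and glmQLFTest), with TMM scaling, the low-count filter filterByExpr and Benjamini-Hochberg adjustment, at a threshold of 0.05. All 23 libraries entered 1 fit with 4 groups for the line against primary cells (equal weight to both times), for time in primary cells, for time in the line, and for the difference of these time effects. AM against FBS was fitted in the 9 libraries of the 21-day line, and WJ against BUC and the slope on the P number in the 6 libraries of the 50-day primary cells. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM levels used TMM-scaled library sizes, except for genes with no count in a group, where unscaled totals were used, and principal components were computed on log2 CPM with a prior count of 2. Pooled ratios used summed counts over summed library totals with exact conditional binomial intervals at a confidence level of 95%. A level against a group with no count was bounded by 3 counts over the pooled total of that group.

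Depth differed between groups, from 1840606 counts in the shallowest library, in the 50-day primary cells, to 15486372 in the deepest, in the 12-day ones. Rank correlations and genes detected were therefore computed after every library was thinned without replacement to 1840606 counts, the smallest total. Shares of the 100 most abundant genes used the full counts. TMM factors were 0.801 to 0.93 in primary cells, 0.882 to 1.004 in the 165-day line and 1.13 to 1.265 in the 21-day line. The biological coefficient of variation was 7.05% in the 12-day and 36.8% in the 50-day primary cells, where it was 16.8% within WJ and 19.7% within BUC, 27.9% in the 21-day line and 24.2% in the 165-day line. Libraries of a group were compared in pairs over genes with at least 10 counts in the pair. The smallest chi-square per degree of freedom was 2.85, so no pair agreed within counting noise and every library was counted once. Repeat libraries of 1 sample whose counts vary beyond counting noise would not be found this way.

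Library measures were compared by exact permutation tests, or by 100000 resamples where the line was set against primary cells, all two-sided, 9 tests adjusted together. These 9 tests, the counts of shared and non-overlapping genes and the groups by abundance were chosen after the data were seen. Alternatives were DESeq2 1.42.0, RLE size factors, no filter, glmTreat against a fold of 1.5, limma 3.58.1 voom with group weights, thinned counts, a replicate block, subsets by tag, and leaving out each library. Added later were scaling by library totals, separate WJ and BUC groups, leaving out 2 libraries of the 165-day line, and a surrogate variable from sva 3.50.0. Each test was first run on simulated counts with 100 genes changed at each of 2 sizes. For the line against primary cells 71% of genes with a log2 change of 1 and 97% of those with a change of 2 were recovered. These shares were 47% and 84% for time in primary cells, 70% and 92% for time in the line, and 29% and 75% for the difference of time effects. For AM against FBS they were 44% and 82%, and for WJ against BUC 56% and 96%. Unchanged genes made up 13 of 181 calls for the line against primary cells and 9 of 140 for time in primary cells. They made up 9 of 171 calls for time in the line, 6 of 110 for the difference and 6 of 132 for AM against FBS. For WJ against BUC they were 13 of 165, and for the P number trend 7 of 56. Far fewer genes were changed than were called in the larger comparisons, so the shares need not hold there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.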

Results

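Gene expression was measured in cultured bovine mesenchymal stem cells from umbilical cord of Holstein cattle. Mesenchymal stem cells are adherent stromal cells that can be expanded in culture and can give rise to connective tissue lineages. The series held 23 libraries in 4 groups. Primary cells were sampled after 12 days (n = 3) and after 50 days (n = 6) in culture. An immortalized line, made from primary cells called WJ by transient transfection of a plasmid for the SV40 large T antigen, was sampled after 21 days (n = 9) and after 165 days (n = 5). The large T antigen is a viral protein that binds and inactivates p53 and the retinoblastoma protein. All 14 libraries of the line came from 1 line. Library names read Male in 1 library at 12 days, F in 1 at 50 days and Mix in 1 at 12 days, which points to more than 1 animal among the primary cells. The labels do not otherwise say which libraries came from separate cultures or animals, and these tags, with 1 library each, were not tested. Hence p-values measure the spread between these libraries, which may be partly technical.

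Total counts per library were 8954270 to 15486372 in the 12-day primary cells and 1840606 to 5920394 in the 50-day primary cells. They were 4141228 to 11382368 in the 21-day line and 3753231 to 13540302 in the 165-day line. Between 11552 and 14758 genes had at least 1 count in a library. Genes were identified only by Ensembl numbers, and none of the 16094 could be given a symbol here, so groups of genes are described by their direction, size of change and abundance.

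The line and the primary cells were apart on the first axis of the data. The first principal component, which held 39.2% of the variance, ran from 22.7 to 84.2 in the 14 libraries of the line and from -89.3 to -38.5 in the 9 primary libraries. It also went with culture time, in opposite directions. Primary libraries lay at -42.3 to -38.5 at 12 days and at -89.3 to -75.9 at 50 days. Those of the line lay at 22.7 to 46.3 at 21 days and at 45.3 to 84.2 at 165 days. The second component, with 18% of the variance, was lower at the shorter culture time in both kinds of cell. The plot of components also shows the 50-day primary libraries apart by the WJ or BUC tag of their names.

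**Figure D1:**
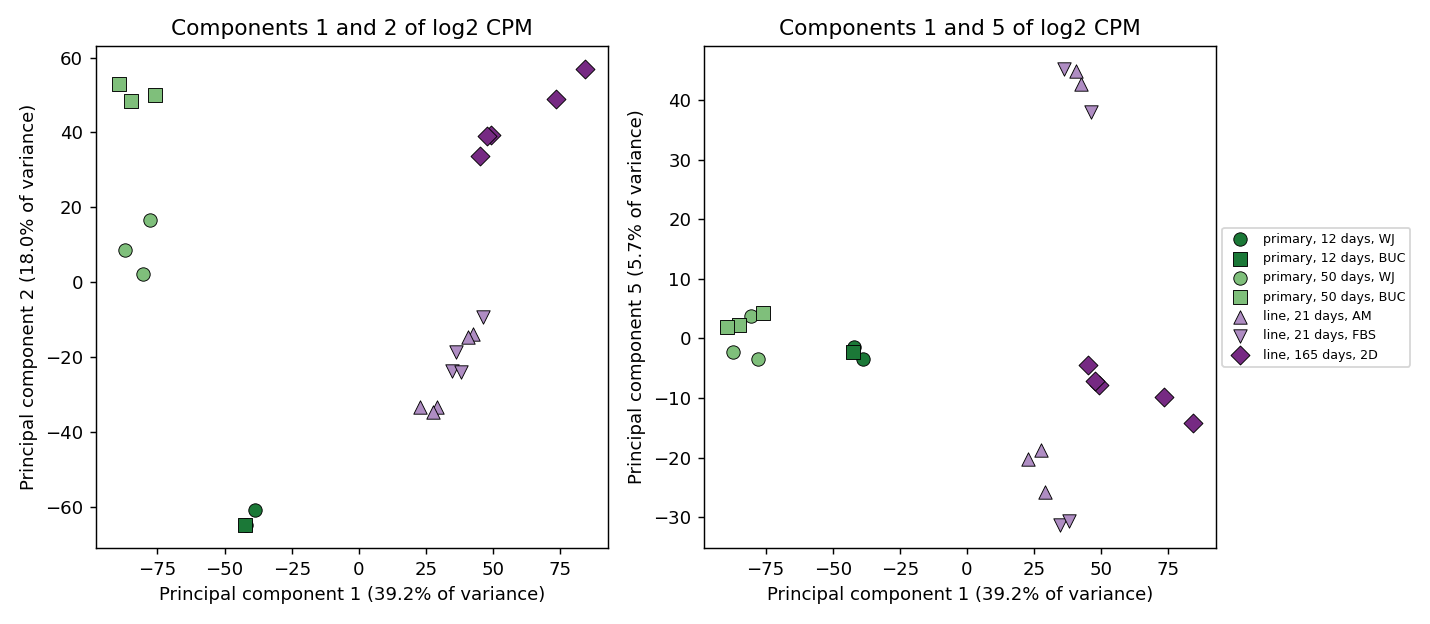
Principal components of log2 CPM over 11489 genes, 1 point per library. The left panel plots component 2 (18% of variance) against component 1 (39.2%), with colour for the group and shape for the tag in the library name. The right panel plots component 5 (5.7%), on which the 9 libraries of the 21-day line lie at -31.4 to -18.7 or at 38 to 45.3.

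At an equal depth of 1840606 counts per library, each of the 23 libraries had its highest rank correlation with a library of its own group. Spearman's rho across genes averaged 0.982 among the 12-day primary libraries, 0.971 among the WJ and 0.97 among the BUC libraries at 50 days, 0.959 within the 21-day line and 0.961 within the 165-day line. Between the line and the primary cells it averaged 0.899 for 21 against 12 days, and 0.844 and 0.831 for the 165-day line against the 50-day WJ and BUC libraries. Genes are not independent replicates, so these values describe similarity and carry no test.

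**Figure D2:**
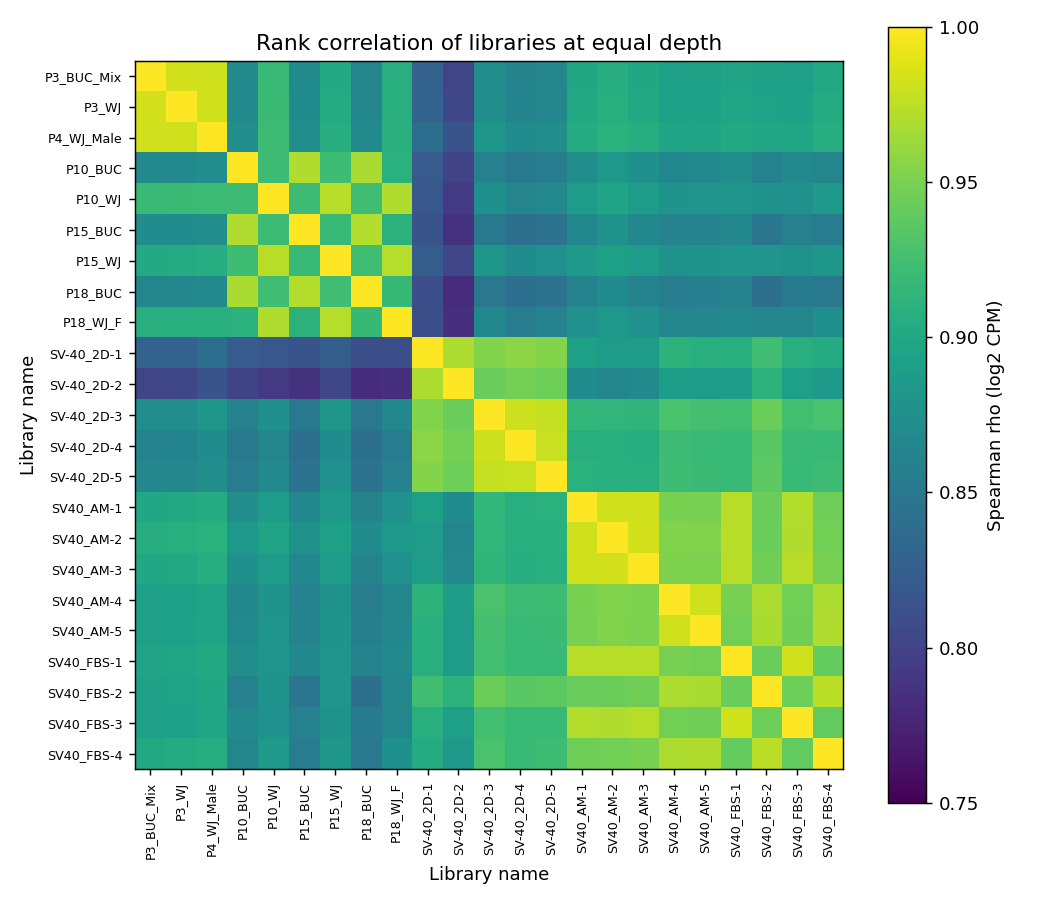
Spearman's rho across genes between each pair of the 23 libraries, all thinned to 1840606 counts, with library names on both axes and rho as colour. The lightest blocks are the 12-day primary libraries (mean 0.982), the WJ and BUC libraries at 50 days (0.971 and 0.97) and blocks within each time of the line.

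The first comparison asked what distinguished the immortalized line from primary cells. In the line, 3882 genes were higher and 3753 were lower, 66.5% of the 11489 genes tested. The median log2 fold change was 0.91 among the higher and -0.91 among the lower genes. At least 4-fold differences were found in 603 higher and 424 lower genes, and at least 8-fold in 272 and 150. All 14 libraries of the line lay above all 9 primary libraries in 505 genes and below them in 645, together 10% of genes. Random labels on independent libraries would give 0.000245%, but all libraries of the line came from the same line.

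Among the genes with the largest rise, ENSBTAG00000021923 stood at 51.8 ± 37.7 CPM (SD, n = 9) in the 21-day line and 144 ± 42 CPM (SD, n = 5) in the 165-day line. Its level was 0.181 ± 0.255 CPM (SD, n = 3) in the 12-day and 0.435 ± 0.529 CPM (SD, n = 6) in the 50-day primary cells. The log2 fold change of the line over primary cells was 8.38 with a standard error of 0.63 (adjusted p = 1.63e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without replicate 2 at 12 days it was 9.22. ENSBTAG00000014078 was at 11.9 ± 10.5 CPM (SD, n = 9) and 21.1 ± 15.8 CPM (SD, n = 5) in the line. Both of these genes were uneven within the 21-day line. Replicates 1, 2, 3, 6 and 8 held 106 to 219 counts of the former and 9 to 30 of the latter, and replicates 4, 5, 7 and 9 held 519 to 1716 and 161 to 302. At 165 days the latter had 289 and 119 counts in replicates 1 and 2, whose totals were 7979762 and 3753231, and 90 to 132 counts in the other 3 libraries, which were deeper. It had 4 counts in total in the primary cells, all in replicate 2 at 12 days, against 1719 in the line. The ratio of these pooled counts per total was 233, with an exact 95% interval from 90.8 to 856 that covers counting error only. Without replicate 2 at 12 days no primary count was left, and the level in the line was at least 250-fold higher, with 3 counts over the other primary libraries as the floor.

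Among the genes with the largest fall, ENSBTAG00000009405 was at 24.2 ± 1.47 CPM (SD, n = 3) in the 12-day and 18.3 ± 19.6 CPM (SD, n = 6) in the 50-day primary cells, where single libraries ranged from 1.06 to 47.2 CPM. This range followed the tag, with 5 to 10 counts in the 3 BUC and 72 to 81 in the 3 WJ libraries. In the line it had 12 counts in all 14 libraries together, and the pooled ratio of primary cells over the line was 160 (exact 95% interval 91.1 to 310). ENSBTAG00000009979 was at 8.41 ± 0.966 CPM (SD, n = 3) at 12 days and 25.4 ± 6.32 CPM (SD, n = 6) at 50 days in primary cells, and had 7 counts in the line. Its pooled ratio of primary cells over the line was 193 (exact 95% interval 93.4 to 483), and 309 without replicate 5 of the 165-day line, which held 3 of the 7 counts. It also rose between 12 and 50 days in primary cells, by 1.59 on the log2 scale with a standard error of 0.36 (edgeR adjusted p = 0.001).

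More genes were detected in the line. At equal depth, 12494 ± 216 genes (SD, n = 9) had a count in the 21-day line and 12242 ± 87.1 (SD, n = 5) in the 165-day line, against 11686 ± 44.5 (SD, n = 3) and 11533 ± 135 (SD, n = 6) in the 12-day and 50-day primary cells. The libraries of the 21-day line fell into separate ranges, 12228 to 12404 and 12662 to 12752. The difference between the line and primary cells was 820 genes (two-sided permutation p = 1e-05, the smallest that 100000 resamples give, adjusted p = 9e-05 over 9 tests of library measures), and every library of the line was above every primary library. The resamples treat libraries as independent, but all libraries of the line came from the same line, so the p-value does not speak for other lines. Whether molecular identifiers were collapsed is not given, so equal counts need not mean equal numbers of molecules.

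The genes that distinguished the line were partly shared between early and late samples. The 21-day line against 12-day primary cells and the 165-day line against 50-day primary cells use no library in common. The early comparison called 2677 genes higher and 3176 lower, and the late one 3939 higher and 3732 lower. Both called 1437 genes higher and 1692 lower, where independent lists would share 918 and 1032. Opposite calls were made for 361 genes that were higher early and lower late and for 641 that were lower early and higher late, where independent lists would give 870 and 1089. The fold changes correlated across genes with Pearson's r of 0.41 and Spearman's rho of 0.4. With scaling by library totals alone, 66.9% of the genes called for the line against primary cells were higher in place of 50.8%, so directions are relative to the TMM scale. The line was the only one studied and the days in culture of line and primary cells did not match, so neither can be separated from immortalization. The line was made from WJ cells, while some primary libraries were named BUC. With only the WJ primary libraries 7258 genes were called for the line against primary cells, 6631 of them also called in the main fit.

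**Figure D3:**
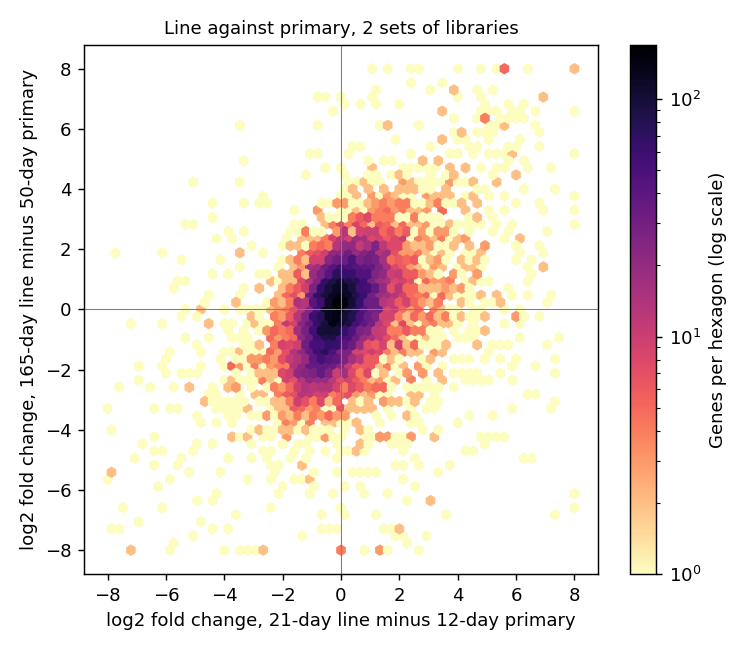
Log2 fold changes of 11489 genes in the 165-day line over 50-day primary cells (vertical) against those in the 21-day line over 12-day primary cells (horizontal). Colour is the number of genes per hexagon on a log scale, and values beyond 8 or below -8 are drawn at that edge. Pearson's r across genes was 0.41.

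The second comparison asked what changed with time in culture in primary cells. From 12 to 50 days, 2258 genes rose and 2853 fell, 44.5% of the genes tested by edgeR. The balance of directions depended on the fit. As fitted 44.2% of the called genes rose, against 52.2% with RLE size factors, 35.7% with library totals alone and 53.1% with TMM in a fit of only the 2 groups. DESeq2, which also changes the test and the filter, gave 53.7%. The median log2 fold change was 1.31 among the rising and -0.96 among the falling genes, and 714 rose and 355 fell by at least 4-fold. Of the 10489 least abundant genes, 1334 rose and 1253 fell by at least 2-fold as fitted, and 1175 rose and 1594 fell with library totals alone. All 6 libraries at 50 days lay above all 3 at 12 days in 1846 genes and below in 2945, together 41.7% of genes. Random labels on independent libraries would give 2.38%. The 3 at 12 days were close to each other, with a biological coefficient of variation of 7.05% against 36.8% at 50 days. The excess over 2.38% therefore does not measure an effect of time alone. A group of 21 genes had no count in the 3 libraries at 12 days, whose 35838241 counts allow a level of up to 0.0837 CPM, and a mean of at least 5 CPM at 50 days, up to 81.9 CPM. Of these, 5 reached that level in each of the 6 libraries at 50 days, and the opposite pattern was found in 4 genes.

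The 50-day libraries of each tag were also set against the 12-day libraries, which held both tags. These are not comparisons within a tag, so a standing difference between WJ and BUC cannot be told apart from time in them. With the WJ and BUC libraries at 50 days fitted as separate groups, a choice made after the data were seen, 1671 genes rose and 2339 fell in WJ, and 2415 rose and 3060 fell in BUC, each against the same 3 libraries at 12 days. By at least 4-fold, 482 rose and 367 fell in WJ, and 791 rose and 537 fell in BUC. Mean rank correlation with the 12-day libraries was 0.911 for WJ and 0.87 for BUC at 50 days, a difference of 0.0409 (two-sided exact permutation p = 0.1, the smallest that 20 splits of 3 against 3 allow, adjusted p = 0.129). The 100 most abundant genes of a library took 32.8% ± 0.896 (SD, n = 3) of its counts at 12 days and 37.1% ± 1.65 (SD, n = 6) at 50 days. That share was higher in 6 of 6 libraries at 50 days (two-sided exact permutation p = 0.0119, the smallest that 84 splits allow, adjusted p = 0.0214). The 50-day group included the shallowest library of the series. Fitted on the 9 primary libraries alone, the 2 times differed in 4524 genes, and a slope on the P number of the names called 3233.

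The third comparison followed the line from 21 to 165 days. In that span 3201 genes rose and 3284 fell, 56.4% of the genes tested by edgeR. All 5 libraries at 165 days had the tag 2D in their names, and none of the 9 at 21 days had it. Time in the line can therefore not be separated from what this tag stands for. Changes of at least 4-fold were found in 207 rising and 259 falling genes, and of at least 8-fold in 53 and 59. All 5 libraries at 165 days were above all 9 at 21 days in 1929 genes and below in 1771, together 32.2% of genes. Random labels on independent libraries would give 0.0999%, but these libraries came from the same line. With scaling by library totals alone, 27.4% of the called genes rose in place of 49.4%. With the FBS libraries alone at 21 days 1952 genes rose and 3057 fell, and with the AM libraries alone 2594 rose and 3529 fell.

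Abundant transcripts moved upward in the line with time. Of the 100 genes with the highest mean level, 68 rose and 7 fell from 21 to 165 days, and 21 rose by at least 2-fold. Of the 900 next most abundant genes, 465 rose and 174 fell, while 2668 rose and 3103 fell among the 10489 below them. The median log2 fold changes of these 3 groups were 0.61, 0.36 and -0.05. With library totals alone, 48 of the 100 rose and 20 fell, 296 of the next 900 rose and 275 fell, 1438 of the rest rose and 4437 fell, and the 3 medians were 0.28, 0.04 and -0.37. On that scale 10 of the 100 rose by at least 2-fold. The share of counts in a library's 100 most abundant genes was 29.3% ± 1.72 (SD, n = 9) at 21 days and 33.8% ± 1.93 (SD, n = 5) at 165 days (two-sided exact permutation p = 0.000999 over 2002 splits, adjusted p = 0.00225). Replicates 1 and 2 at 165 days stood at 35.4% and 36.1%. The others stood at 31.6% to 33.3%, which overlaps the 25.9% to 32.1% at 21 days. The splits treat libraries of the same line as independent, so this p-value may be too small.

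The line was less like primary cells at 165 days than at 21 days. The mean rank correlation of a library with the 9 primary libraries at equal depth was 0.88 ± 0.00578 (SD, n = 9) at 21 days and 0.841 ± 0.0308 (SD, n = 5) at 165 days, and all 9 libraries at 21 days were above all 5 at 165 days. The difference was 0.0391 (two-sided exact permutation p = 5e-04, the smallest that 2002 splits allow, adjusted p = 0.00222). Replicates 1 and 2 of the 165-day line stood apart from the other 3, at 0.822 and 0.797 against 0.858 to 0.868. Without these 2 libraries, an alternative added after the data were seen, the difference was 0.018 (two-sided exact permutation p = 0.00455). The splits treat libraries of the same line as independent, although they fell into sets at both times, so these p-values may be too small. The tag 2D went with the later time here too, so the difference cannot be assigned to time alone.

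Time in culture had different effects in the line and in primary cells. The difference between the 2 time effects passed the test in 5598 genes, 2877 with the higher effect in the line and 2721 with the lower. The 2 time effects, which share no library, correlated across genes with Pearson's r of 0.11 and Spearman's rho of 0.08. Both called 754 genes higher and 957 lower, where independent lists would share 629 and 815. Opposite calls were made for 463 genes that rose in primary cells and fell in the line and for 819 that did the reverse, where independent lists would give 645 and 795. Of the 2993 genes called for both time effects, 57.2% changed in the same direction. The spans differed, from 12 to 50 days in primary cells and from 21 to 165 days in the line, so the test does not compare equal times. Within the line the tag 2D also went with the later time. With scaling by library totals alone 40.8% of the called differences were positive in place of 51.4%, with RLE size factors 44.6% and with DESeq2, which also changes the test and the filter, 44%.

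Within the 50-day primary cells, libraries tagged WJ and BUC differed in 2201 of the 9075 genes tested by edgeR, with 970 higher and 1231 lower in WJ. Without replicate 2 the number higher in WJ was 638. At least 8-fold differences were found in 82 higher and 187 lower genes. The 12-day libraries held 1 named BUC and 2 named WJ, which correlated with each other at 0.982 at equal depth, against 0.918 between WJ and BUC at 50 days.

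In the 21-day line, libraries tagged AM and FBS in their names differed in 45 of the 10597 genes tested by edgeR, 39 higher and 6 lower in AM, and 1001 genes had an unadjusted p under 0.05. DESeq2 called 195 genes, 71.8% of them higher in AM against 86.7% by edgeR. Leaving out any single library of replicates 1 to 8 left 6 to 20 genes, and leaving out replicate 9 left 46. With the number in the library name as a block, edgeR called 0 genes, with 1169 at an unadjusted p under 0.05. The 9 libraries fell into 2 sets that cut across the tags, as component 5 of the plot of components shows. With 1 surrogate variable as a covariate, an alternative added after the data were seen, 515 genes were called, 331 higher and 184 lower in AM. The surrogate variable followed these sets, at -0.32 to -0.26 in 1 set and at 0.36 to 0.39 in the other. The meaning of AM is not given in the sources used here.

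Expression in the 50-day primary cells showed no trend with the P number of the library names that passed the test. Over the P numbers 10, 15 and 18, edgeR called 0 of 7825 genes, with 139 genes at an unadjusted p under 0.05, and DESeq2 also called 0. With the WJ or BUC tag as a covariate edgeR called 0 genes, with 560 at an unadjusted p under 0.05. On simulated counts of the fit without the tag, 0% of genes with a log2 change of 1 between the lowest and the highest P number, and 49% of those with a change of 2, were recovered, and recovery with the tag was not simulated.

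**Figure D4:**
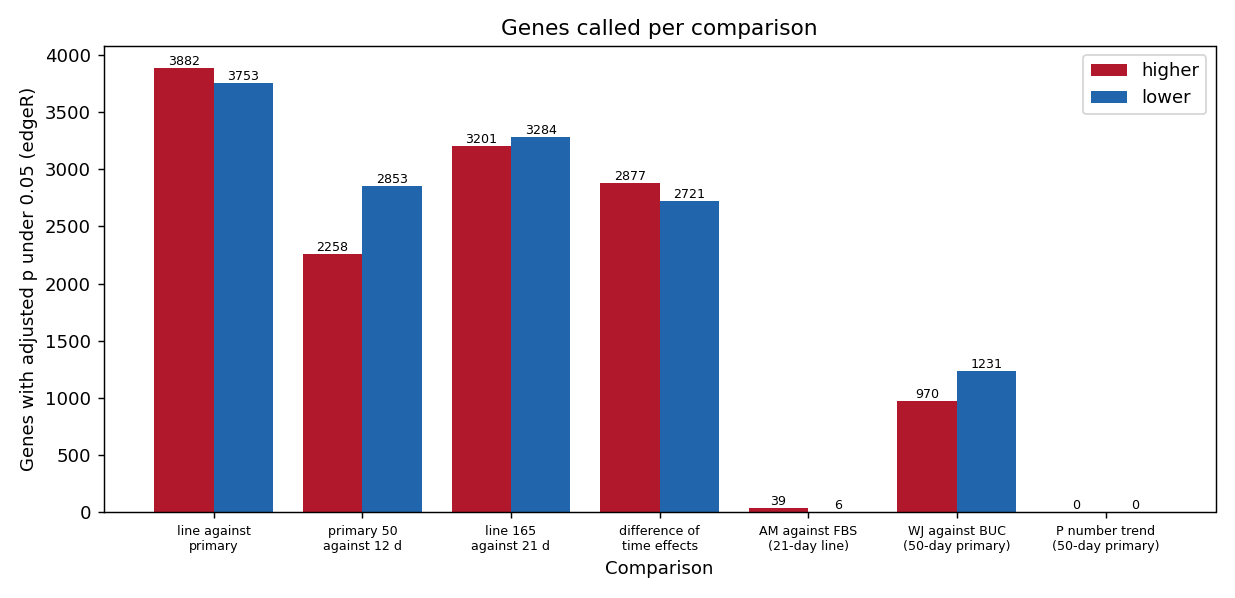
Numbers of genes called higher and lower by edgeR (adjusted p under 0.05) in each of the 7 comparisons. The line against primary cells gave the largest numbers, 3882 and 3753, and the P number trend gave 0.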

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

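The difference of the time effects and the search for libraries far from the rest of their group were fixed before the data were examined. The effect of time in culture differed between the line and the primary cells in 5598 genes by the test of the difference itself. Of 100 draws of the day labels within each kind of cell, 1 gave as many, the real one, and the highest of the others gave 976. Because the draws treat libraries as independent, they cannot exclude chance differences between a few cultures or batches. The line and the primary cells also differed in the days compared, and the cause of the difference was not tested.

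Of 29 checks, each of 1 measure in 1 group of libraries, 3 found a value far from the others. All 3 concern IDs picked from these data by their fold change, so the nominal rate of about 1 in 20 does not apply to them. In log2 CPM, ENSBTAG00000021923 was at 7.76 in replicate 2 of the 165-day line, with the nearest other library at 7.08. ENSBTAG00000009405 was at -1.53 in replicate 3 of the 165-day line, where it had 1 count and the other libraries, at -1.88, had none. ENSBTAG00000009979 was at -0.864 in replicate 8 of the 21-day line, with the nearest other at -1.4, at a level of at most 2 counts per library. The last 2 lie at the limit of the counts.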

How the results depend on the processing

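Scaling by library totals, the subsets with WJ and BUC apart, leaving out replicates 1 and 2 of the 165-day line, the surrogate variable, and the correlations with their alternatives, were chosen after the data were seen. The 4 IDs kept their direction and an adjusted p under 0.05 in all alternatives run. They were picked from the same counts by adjusted p and largest fold change, so this could hardly come out otherwise. The balance of higher and lower calls turned under some alternatives. For time in primary cells it went from 2258 higher and 2853 lower to 2875 and 2479 with DESeq2, 2608 and 2389 with RLE, 2401 and 2123 in the fit of 2 groups, and 2484 and 2340 with the tag as a covariate. For the difference of time effects it went from 2877 and 2721 to 2593 and 3305 with DESeq2, 2473 and 3076 with RLE, 2042 and 2189 thinned, and 2234 and 3245 with library totals. For the line against primary cells it turned to 1933 and 1950 against a fold of 1.5 and to 2677 and 3176 at the early times alone. It turned to 3422 and 3283 with voom for time in the line, and to 1125 and 1108 with library totals for WJ against BUC. Among genes called both for the line against primary cells and in a fit of 1 pair of times, 186 had the opposite sign in the early and 83 in the late pair. Counts of called genes stayed within 1.5 times the reported count except as follows, and the cause was not tested unless the construction shows it. Testing against a fold of 1.5, which by construction calls fewer genes, left 3883 for the line against primary cells, 2530 for time in primary cells, 2956 for time in the line, 3617 for the difference of time effects, 5 for AM against FBS and 947 for WJ against BUC. The slope on the P number over the 9 primary libraries called 3233 genes for time in primary cells, and the 2-group fit on them 4524. For AM against FBS, DESeq2 called 195, 1 surrogate variable 515, the leave-one-out fits 6 to 46 and the block below 0.

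Leaving out 1 library gave 7230 to 7643 genes for the line against primary cells, 4138 to 5151 for time in primary cells, 6004 to 6499 for time in the line, 4948 to 5650 for the difference and 1594 to 2079 for WJ against BUC. It gave 0 for the P number trend, and 0.028 to 0.046 for the difference in correlation with primary libraries. Without replicates 1 and 2 of the 165-day line 7251 genes were called for the line against primary cells, 5583 for time in the line and 5202 for the difference. Thinning to the smallest library gave 6049, 3811, 5240 and 4231 for the first 4 comparisons, with fewer genes past the filter. Library totals shifted the median log2 fold change of all genes from 0.034 to 0.299 (line against primary), from -0.078 to -0.194 (primary time), from -0.009 to -0.331 (line time) and from 0.01 to -0.192 (difference). RLE factors moved the last to -0.117 and DESeq2 to -0.252, and DESeq2 moved the first to 0.136. For primary time RLE gave 0.023 and DESeq2 0.049.

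The replicate numbers of the titles did not pair the samples. Deviations of same-numbered libraries correlated at -0.02 to 0.01 between primary times and at -0.2 to 0.18 between times of the line. With that number as a replicate block the counts were 7300, 4608, 6067 and 5250, Pearson's r of the time effects 0.04 and that of the early and late line effects 0.35. With the library-name number as a block AM against FBS gave 0 genes by edgeR, with 1169 at an unadjusted p under 0.05 and pair correlations of -0.48 to 0.49. With the P number as a block WJ against BUC gave 2037. The planned gene lists and their alternatives were not run, since no ID had a symbol.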

Other observations

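The tests of the AM or FBS tag as the source of the 2 sets in the 21-day line and the 3 tests on the WJ and BUC libraries were chosen after their results had been seen, as was the comparison in the next paragraph. The patterns themselves were found in these data.

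Every library of the line was closer in rank correlation to the 50-day WJ libraries than to the 50-day BUC libraries, in 14 of 14 libraries, by 0.001 to 0.024. The line was made from WJ cells, but this closeness was not particular to it. The 12-day primary libraries, 1 of them named BUC, were also closer to the 50-day WJ libraries, at a mean of 0.911 against 0.87.

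The 9 libraries of the 21-day line fell into 2 sets that no label used here names. Replicates 1, 2, 3, 6 and 8 lay at -24.9 to -22.2 on the first component within the group, which held 54.9% of its variance, and replicates 4, 5, 7 and 9 at 25.6 to 32.5. At equal depth 12228 to 12404 genes were detected in the former set and 12662 to 12752 in the latter, and the cause was not tested. Library depth is argued against, since the gap was at least 0.823 of the range with all 9 libraries at equal depth, in 20 of 20 thinnings. The tag is argued against by 4 of 9 libraries on the side of the other tag. Without the 100 most abundant genes the gap was 0.836. On log2 CPM abundant genes get no extra weight, so leaving out 100 could change little and cannot decide on a few abundant genes. A difference between library or culture batches, clones or passages of the line stays open, since the labels give none of these, and no biological explanation was tested.

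The 5 libraries of the 165-day line also fell apart, with replicates 1 and 2 at -29.1 and -43.3 and the others at 22.2 to 26.6 on a component with 75.3% of the variance. The 2 had totals of 7979762 and 3753231 counts. Depth is argued against by a gap of at least 0.767 of the range in 20 thinnings. The gap was 0.736 without the 100 most abundant genes, which for the reason given above cannot decide on a few abundant genes. Batch and culture stay open here too, and no biological explanation was tested.

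The WJ and BUC libraries were far apart at 50 days and close at 12 days. With all 9 primary libraries at equal depth, and over the genes past the low-count filter in them alone, rank correlation at 50 days was 0.966 within tags and 0.883 between them. The difference of 0.082 argues against the lower depth at 50 days. The only BUC library at 12 days, named BUC_Mix, differed from the 2 WJ libraries there by 0.95 of the mean squared difference between these. A library of the same material as WJ and a divergence of the cultures after 12 days would both give this, so they cannot be told apart. For the same reason a constant difference between WJ and BUC stays open, although the 2201 genes called at 50 days had differences at 12 days with a slope of -0.001 on those at 50 days.

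Other splits of the libraries were fitted by edgeR for each count. For the line against primary cells 7635 genes were called and 1 of 100 draws, the real one, gave as many, with 3511 as the highest other. For time in the line, with 6485 genes, 1 of 100 splits gave as many, with 2507 as the highest other. The real groups thus gave more calls than the other divisions drawn. Because the draws treat libraries as independent, they cannot exclude chance differences between a few cultures or batches. For time in primary cells, with 5111 genes, 1 of 84 splits gave as many. The highest other split gave 3715 and set the 3 BUC libraries at 50 days against the rest, which points to the structure by tag. For AM against FBS, with 45 genes, 6 of 100 splits gave as many. The highest other gave 3875 and was the division into the 2 sets of the 21-day line. The next 2, with 1042 and 986 genes, were that division with 1 library moved. Such splits carry a structure of the samples, so the share cannot decide on AM against FBS, and chance is not excluded. For WJ against BUC the 10 splits are too few for a share under 0.05, with 2201 genes in the real split and 1 as the highest other. For the P number trend, with 0 genes by edgeR, 139 at an unadjusted p under 0.05 and 0 by DESeq2, all 90 arrangements gave as many and the highest other gave 8.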
